A study of Homo sapiens with 4 samples.

How the data were processed

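RNA was sequenced in 4 libraries of SH-SY5Y cells, 2 undifferentiated and 2 differentiated. Per the labels' protocols, total RNA was treated with DNase, ribosomal RNA was removed with magnetic beads, cDNA was made with tailed random primers, and each library was sequenced in 1 lane of an Illumina HiSeq 2000. The labels do not say whether the replicates came from separate cultures, so the authors' q-values may measure technical spread.

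Per the submitters' processing notes, TopHat2 2.0.8 and Cufflinks 2.0.2 were used with the human genome build hg19. The authors deposited 1 FPKM (fragments scaled to transcript length and to the number mapped) per gene and group, with a log2 fold change, a test statistic, a p-value and a q-value, per the file headers. How the 2 libraries of a group were combined, how libraries were scaled and which gene annotation was used are not given in the sources used here. The table has 23576 rows, of which 12810 were tested by the authors; 10580 were marked as not tested, 159 as having too little data and 27 as failed. The deposited p-value equalled the two-sided normal p of the deposited statistic in 12750 of 12750 tested rows with values above 0 in both groups (tolerance 0.001). The deposited q-value differed from a Benjamini-Hochberg adjustment over the tested rows by at most 1.48e-06. In 23 failed rows the deposited fold was not the log2 ratio of the 2 FPKM values, and those rows were not used. A further 28 rows have a date in place of a gene name, 9 of them called, and were left out because their gene is not known. The locus of a row can span several genes, and 6346 rows share a locus with another row, so values of overlapping or antisense genes are uncertain. Loci are hg19 as listed; starts were raised by 1, since the end less the listed start equalled the gene length in 1923 loci and that length less 1 in 250.

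The planned test was limma on the values of each library, with camera for gene lists. It needs values per library, and the table holds group values, so it was not run. The authors' calls (q below 0.05) were used in its place, over genes with a mean of at least 1 FPKM. A standard error was taken from each gene as the size of its log2 fold change over that of its statistic; its median was 0.362. The fold change less the median over 11169 genes was divided by this error, and its two-sided normal p was adjusted by Benjamini-Hochberg. Calls above or below the median gene use an adjusted p below 0.05. This inherits the authors' variance model, and a gene with a large implied error cannot be called. For each of 30 gene lists, the members called, the members adjusted over the list alone and the median log2 fold change were computed. The median of each list with at least 5 tested members was placed among 10000 random lists of the same size, matched in 10 bins of mean FPKM, as a description of these libraries. Of 1076 list entries, 4 were matched through another symbol of the reference tables and 13, all encoded by the mitochondrial genome, matched no row.

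Genes were named by a rule fixed with the lists before the data were examined. It took the 10 largest rises and 10 largest falls among called genes with at least 5 FPKM in the higher group, leaving out small RNAs, clone-based names and pseudogenes. It added up to 4 called members of each list with the largest change, or the 2 most abundant members where none was called, and a fixed set that included NTRK2, RARB, CYP26A1, MYCN, MKI67, TH, CHAT and VIM. The part of the rule that asked for separation between the libraries of each group could not be applied. This gave 127 genes, of which 6 are not reported here.

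Transcript lengths and exon counts came from GENCODE release 29 on GRCh38, matched by symbol, and no coordinates were taken from it. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9. The test relative to the median gene was tested on simulated data for this comparison with 11169 genes and a shift of -0.5, found as -0.496. The simulated noise was drawn from the same implied standard errors that the test uses, so it cannot show whether those errors are right. Every simulated gene also had the same shift, whereas in the data the median fold varied with expression. The simulation therefore cannot show how many false calls come from taking 1 median from all genes. With 200 genes changed in all, split evenly between log2 folds of 1 and 2, the test recovered 29% of the former and 77% of the latter. It called 3 unchanged genes. Of 40 simulated lists with no effect 4 fell outside the central 95%, and 40 of 40 lists moved by a log2 of 1 lay above it. Alternatives covered the pseudocount, the filter on low values, the scaling, the threshold and small RNAs.

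Depth is unknown, since the table holds no counts, so no counting interval or detection floor is given. Cufflinks estimates FPKM over transcripts, and whole reads were not recovered from the low values. Small RNAs take 67.3% of the summed FPKM in undifferentiated and 64.6% in differentiated cells. A value listed at 0 may be a failed estimate. All 9 major histocompatibility complex region genes looked at, chosen after their values were seen, were at or under 0.05 FPKM in both groups, among them the ribosomal protein gene RPS18. They are read only as listed low, and the interferon response genes among them could not be tested.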

Results

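Gene expression was measured by RNA sequencing in SH-SY5Y cells, a human neuroblastoma line of sympathoadrenal origin that takes on neuron-like features in culture. The 4 libraries fall into 2 groups of 2. Undifferentiated cells were collected on day 0. Differentiated cells were collected on day 16, after 7 days of retinoic acid at 10 µM and a further 9 days of brain-derived neurotrophic factor (BDNF) at 20 ng/mL without serum. The values are 1 FPKM per gene and group, so the spread between the 2 libraries of a group cannot be given, and the depth of each library is unknown. The error given for a fold change is the standard error implied by the authors' own test statistic, and q-values are the authors' unless said otherwise.

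The design asks how expression differs before and after neuronal differentiation. Differentiated cells had higher expression of NTRK2, the receptor for BDNF, and of RARB, a retinoic acid receptor gene that retinoic acid itself induces. Most tested genes for neurites, synapses and ion channels were not called, and the medians of these lists lay above those of matched random lists. They had lower expression of genes for mitosis, DNA replication, histones and ribosome production. The inhibitors of differentiation ID1 and ID2 were among the largest falls. In the authors' deposited table NTRK2 rose from 0.383 to 5.76 FPKM, a log2 fold change of 3.91 with an implied standard error of 0.645 (q = 8.55e-08). ID2 fell from 29.1 to 1.49 FPKM in the authors' deposited table, a log2 fold change of -4.29 with an implied standard error of 0.583 (q = 3.81e-11).

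Of 12810 genes tested in the authors' deposited table, 3893 were called at q below 0.05, with 311 higher and 3582 lower in differentiated cells. Among the 11200 tested genes with a mean of at least 1 FPKM, the authors' deposited table called 3764, of which 246 were higher and 3518 lower. The log2 fold changes were not centred on 0. Over the 11169 of these genes with a value above 0 in both groups and a usable statistic, the median was -0.62, the quartiles were -0.96 and -0.23, and 84.0% were negative. Each gene was therefore also compared with the median gene, by a normal test of its fold change less the median with the implied standard error and Benjamini-Hochberg adjustment. That test called 1139 genes, 630 above the median gene and 509 below it. The median log2 fold itself varied with expression, from -0.39 in the lowest expression bin to -0.72 in the highest. The same median of -0.62 was taken from every gene. Counts above the median gene can therefore favour genes of low expression, and counts below it genes of high expression. This holds for the counts given per list too, which were not matched on expression, unlike the random lists. All 246 genes called higher in the authors' deposited table lay above the median gene at an adjusted p below 0.05, and 509 of the lower ones lay below it. Taking a negative median from every fold, with the error kept, moves each higher gene further from 0. Likewise, a gene called below the median gene is further still below 0. These overlaps were therefore nearly fixed in advance and are no separate check. With FPKM rescaled to an equal sum in both groups the split was 895 higher and 313 lower, and with quantile normalization 569 and 472. Small RNAs held 67.3% of the summed FPKM in undifferentiated and 64.6% in differentiated cells. The sum was lower in differentiated cells with them (2044720 to 1189200) and without them (668230 to 420419). The equal-sum scaling therefore does not raise the folds through small RNAs alone. In the paragraphs that follow, "called" refers to the authors' q-value, and calls above or below the median gene are given beside it.

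**Figure D1:**
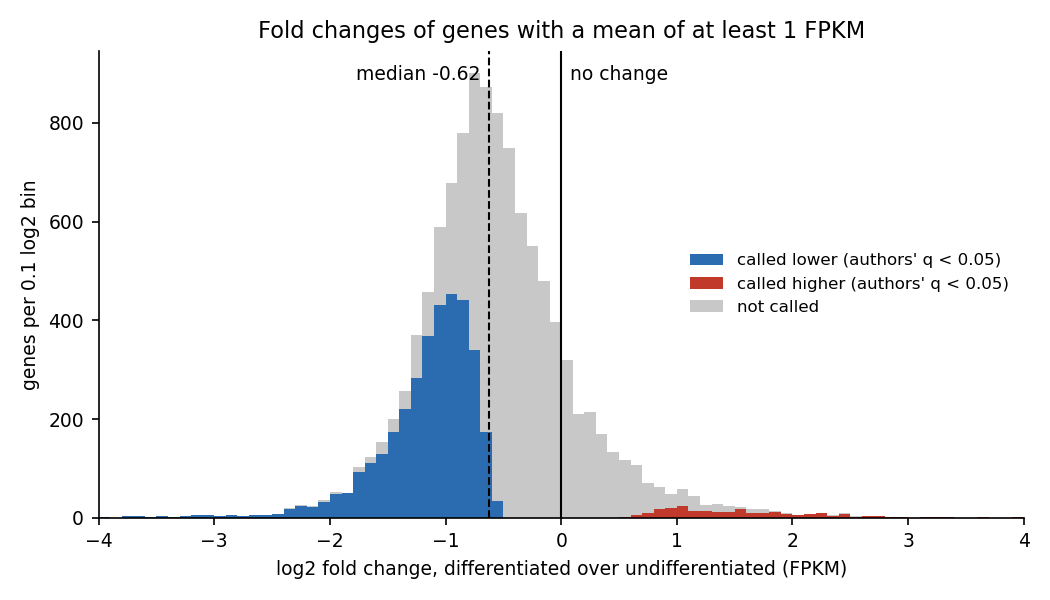
Histogram of log2 fold changes (differentiated over undifferentiated FPKM, x axis) with the number of genes per bin of 0.1 on the y axis, coloured by the authors' call. The dashed line marks the median of -0.62 and the solid line marks no change; 246 genes were called higher and 3518 lower.

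The largest rise by the naming rule was that of H19, an imprinted long non-coding RNA at chromosome 11, 2016406 to 2019065 (hg19). It went from 3.76 to 207 FPKM in the authors' deposited table, a log2 fold change of 5.78 with an implied standard error of 0.281 and a q listed at 0. STMN4, a neuronal microtubule regulator, followed with 4.02, then the growth factor gene FGF1 with 4.00, all from the authors' deposited table. The peptidase gene ECEL1 (3.67), the G protein subunit gene GNG3 (3.66), NELL2 (3.28), the Notch ligand gene JAG1 (3.15) and the metalloproteinase inhibitor gene TIMP3 (2.92) also rose in the authors' deposited table. The largest fall among called genes with at least 5 FPKM in the higher group was that of RORB, a nuclear receptor gene at chromosome 9, 77112252 to 77302117 (hg19), from 14.6 to 0.287 FPKM in the authors' deposited table. Its log2 fold change was -5.66 with an implied standard error of 0.662. The kinase gene SGK1 (-5.54), PRR16 (-4.64), the histone gene HIST1H4F (-4.54), ID2 (-4.29), LRRN3 (-4.03), the endothelin receptor gene EDNRA (-3.93), FLRT3 (-3.79) and ID1 (-3.78) fell in the authors' deposited table. These falls, with that of RORB, also lay below the median gene, with adjusted p from 1.16e-15 for LRRN3 to 0.0422 for HIST1H4F. The loci listed for GNG3, TIMP3, LRRN3 and FLRT3 may span other genes, so fragments counted there are uncertain. That of FLRT3 runs from 13976146 to 16033841 on chromosome 20 (hg19).

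**Figure D2:**
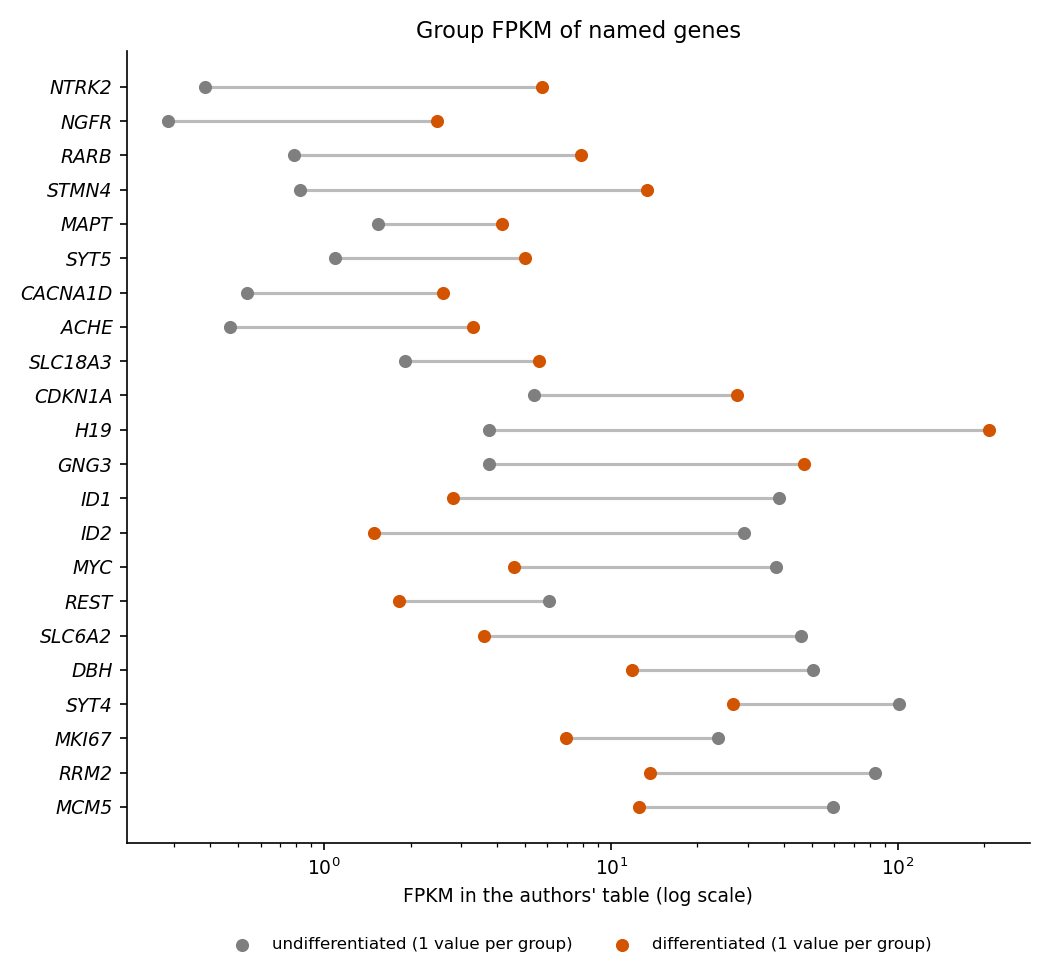
FPKM of 22 named genes in undifferentiated (grey) and differentiated (orange) cells, 1 value per gene and group from the authors' table, on a log x axis. NTRK2 moved from 0.383 to 5.76 and ID2 from 29.1 to 1.49.

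Genes of the cell cycle fell together. All 30 mitotic genes were called lower in the authors' deposited table, and 17 lay below the median gene. Among them, the kinetochore gene CENPF had a log2 fold change of -2.03, ASPM -1.98, BIRC5 -1.79, PLK1 -1.79 and the proliferation marker MKI67 -1.76 in the authors' deposited table. Of 37 DNA replication genes, 31 were called lower in the authors' deposited table and 22 lay below the median gene. The ribonucleotide reductase gene RRM2 went from 83.4 to 13.7 FPKM in the authors' deposited table, and the helicase gene MCM5 from 59.1 to 12.5. TK1 (-2.22) and the DNA methylation factor UHRF1 (-2.15) fell as well in the authors' deposited table. All 46 replication-dependent histone genes were called lower in the authors' deposited table and 33 lay below the median gene; HIST1H3C (-2.27), HIST1H2AH (-2.23) and HIST1H2BF (-2.19) were examples. Medians of these lists were -1.51, -1.62 and -1.65, each below the central 95% of 10000 random lists matched on expression. Adjusted over the list alone, the lower counts were 30, 36 and 46.

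Of 14 cyclin-dependent kinase inhibitor and cell cycle exit genes, 4 were called higher and 2 lower in the authors' deposited table, with 5 above and 0 below the median gene. The inhibitor genes CDKN1A (5.37 to 27.6 FPKM) and CDKN2D (1.48 to 5.94 FPKM) rose in the authors' deposited table, as did the stress gene GADD45A (5.24 to 19.2 FPKM). CDKN2C was called lower there, with a log2 fold change of -1.25 in the authors' deposited table, and did not lie apart from the median gene (adjusted p = 0.323). The list median of -0.24 lay at the 98.7th percentile of matched random lists, and the counts adjusted over the list alone were 4 higher and 3 lower.

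Of 15 retinoic acid response genes that could be tested, 3 were called higher and 3 lower in the authors' deposited table, with 4 above and 1 below the median gene. RARB, at chromosome 3, 25469754 to 25639422 (hg19), rose from 0.782 to 7.87 FPKM in the authors' deposited table (log2 3.33, implied standard error 0.531, q = 2.76e-08). RDH10, which makes retinaldehyde, had a log2 fold change of 1.11 (q = 0.0485) in the authors' deposited table. The retinol transporter gene STRA6 was lower at -1.82 in the authors' deposited table and lay below the median gene. MEIS2 was called lower at -1.08 in the authors' deposited table and did not lie apart from the median gene (adjusted p = 0.303). CYP26A1, which breaks down retinoic acid, was listed at 0 in undifferentiated and 0.415 FPKM in differentiated cells in the authors' deposited table (q = 0.0847). The list median of -0.20 lay at the 99.4th percentile, though within the central 95% when a mean of at least 5 FPKM was required, and adjusted over the list alone the counts were 3 and 3. None of 8 tested HOX genes was called in the authors' deposited table or when adjusted over the list alone. HOXD8 had a log2 fold change of 0.45 (q = 0.481) in the authors' deposited table, and HOXC4 one of -0.09 (q = 0.895) that took a positive sign under each of the 3 other scalings. Those scalings raise log2 folds by 0.62, by 0.78 and by a median of 0.60, so the turn is not particular to HOXC4. The HOX median of -0.04 lay at the 92.8th percentile, with 1 gene above and 0 below the median gene.

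Of 20 neurotrophin receptor and activity-regulated genes, 5 were called higher and 1 lower in the authors' deposited table, and 9 lay above the median gene and 0 below it. NTRK2 lies at chromosome 9, 87283466 to 87638505 (hg19). NGFR, which encodes the low-affinity neurotrophin receptor, rose from 0.286 to 2.47 FPKM in the authors' deposited table (q = 0.000107), and the immediate early gene FOS from 0.333 to 2.04 FPKM (q = 0.00941). SPRY2 was called lower, at -1.29 in the authors' deposited table, without lying apart from the median gene (adjusted p = 0.261). The list median was 0.37, above the central range of matched random lists, and adjusted over the list alone the counts were 5 and 1.

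Neuronal structural genes lay above the median gene more often than below it. Of 37 cytoskeleton and neurite growth genes, 8 were called higher and 4 lower in the authors' deposited table, while 19 lay above the median gene and 0 below it. Besides STMN4, the intermediate filament gene PRPH (1.94) and the tau gene MAPT (1.44) rose in the authors' deposited table. The MAPT row is placed on an alternative haplotype contig of chromosome 17 in the authors' deposited table. Of 29 presynaptic and exocytosis genes, 6 were called higher and 3 lower in the authors' deposited table, with 10 above and 2 below the median gene. SYT5 (2.21) and SYNGR3 (1.82) rose, while the vesicle genes RPH3A (-4.21) and SYT4 (-1.92) fell in the authors' deposited table. Of 19 postsynaptic and receptor genes, the dopamine receptor gene DRD2 (1.68) and the scaffold gene DLG2 (1.31) were called higher and 0 lower in the authors' deposited table, with 5 above and 0 below the median gene. Of 16 voltage-gated ion channel genes, 3 were called higher and 2 lower in the authors' deposited table, with 4 above and 1 below the median gene. The calcium channel genes CACNA2D3 (0.0889 to 3.83 FPKM) and CACNA1D (0.536 to 2.60 FPKM) rose and CACNA2D2 (14.9 to 4.53 FPKM) fell in the authors' deposited table. The potassium channel gene KCNH2 was called lower at -1.34 in the authors' deposited table and did not lie apart from the median gene (adjusted p = 0.147). The medians of these 4 lists were 0.07, 0.19, -0.07 and 0.33, all above the central 95% of matched random lists. The postsynaptic list was no longer above it with a pseudocount of 3 or without the filter on low values, nor the ion channel list with a mean of at least 5 FPKM, where its median relative to the median gene went from 0.96 to 0.06. Adjusted over the list alone, the higher counts were 8, 6, 2 and 3 and the lower counts 4, 3, 0 and 2.

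**Figure D3:**
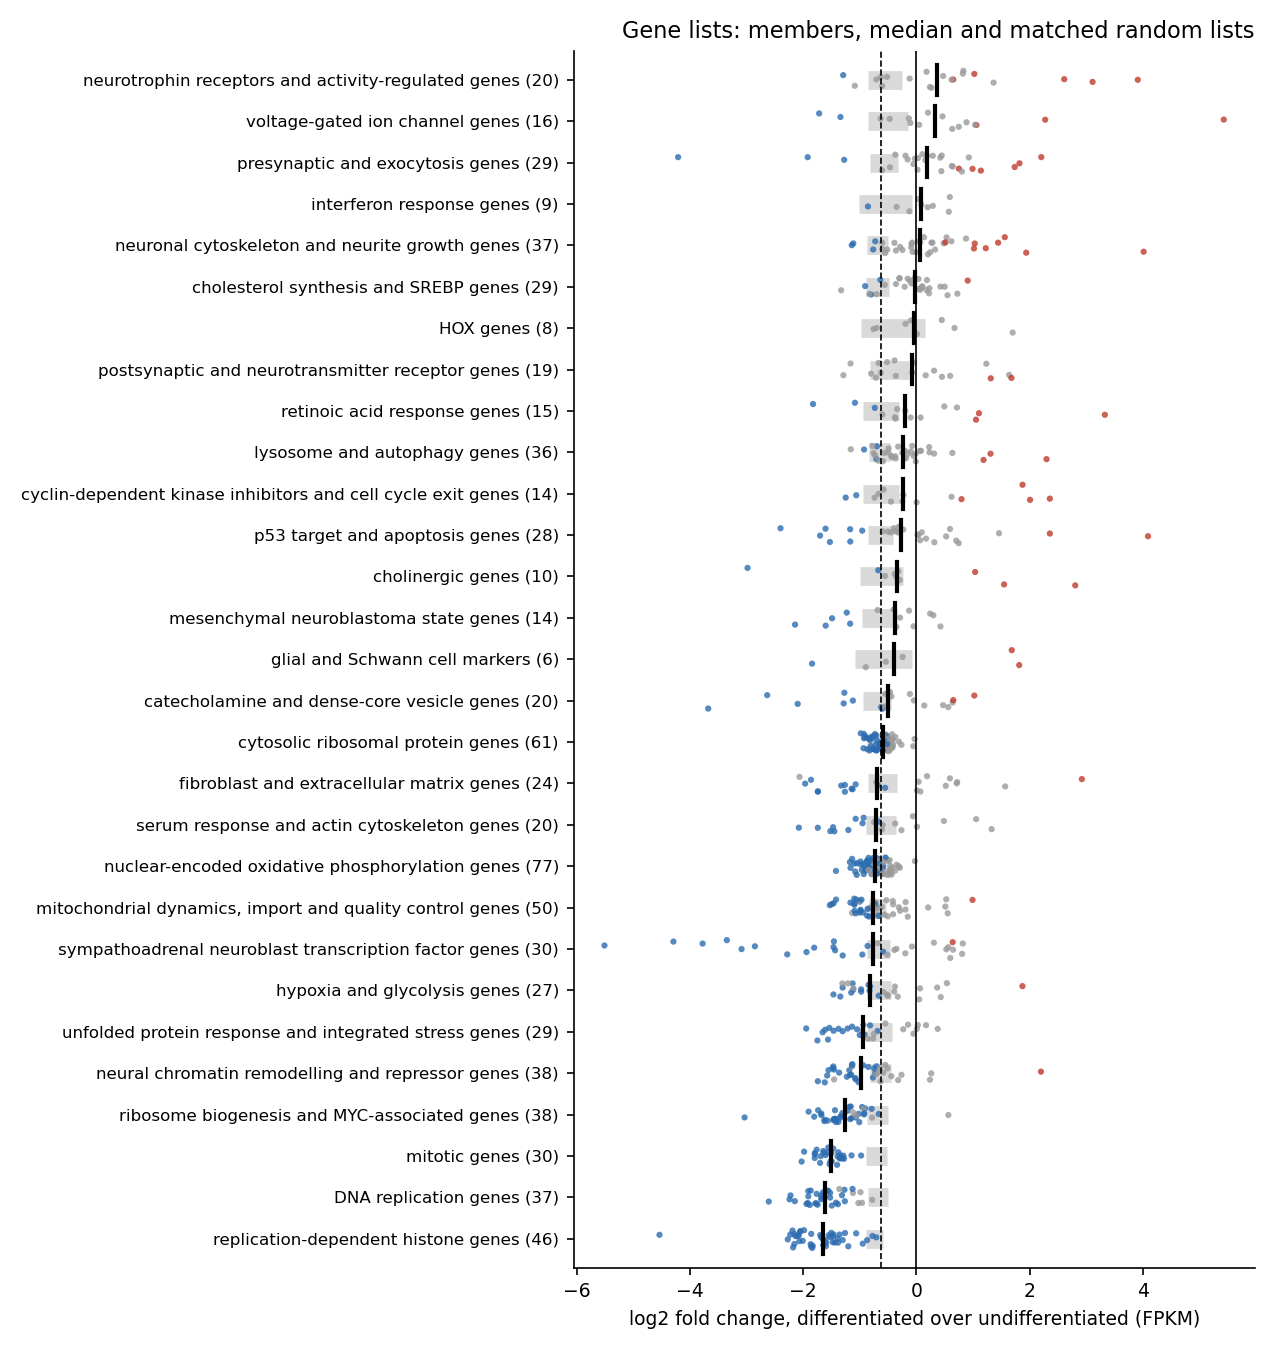
Log2 fold changes (x axis) of the tested members of 29 gene lists (rows, tested members in brackets), red where called higher, blue where called lower and grey where not called by the authors. Black bars are list medians, grey bands the central 95% of matched random lists, and the dashed line the median gene at -0.62; 12 lists lie above their band and 6 below.

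Catecholamine genes moved both ways. Of 20 catecholamine and dense-core vesicle genes, 2 were called higher and 8 lower in the authors' deposited table, and 4 lay above and 4 below the median gene. The noradrenaline transporter gene SLC6A2 fell from 46.0 to 3.60 FPKM in the authors' deposited table, and DBH, which encodes the enzyme that makes noradrenaline, from 50.7 to 11.9 FPKM. CYB561 (-2.63) and the granin gene CHGB (-1.28) fell too in the authors' deposited table. TH, the rate-limiting enzyme gene of catecholamine synthesis, was listed at 0 and 0.202 FPKM in the authors' deposited table and was not tested there. Values this low stand near the background, as the mean of 395 olfactory receptor genes in the authors' deposited table was 0.0114 FPKM in undifferentiated and 0.0773 FPKM in differentiated cells. Of 10 cholinergic genes, 3 were called higher and 2 lower in the authors' deposited table, with 3 above and 1 below the median gene. The acetylcholinesterase gene ACHE (0.470 to 3.29 FPKM), the vesicular acetylcholine transporter gene SLC18A3 (1.92 to 5.62 FPKM) and the receptor gene CHRNA7 (5.50 to 11.3 FPKM) rose in the authors' deposited table. PRIMA1, which anchors acetylcholinesterase, fell from 6.99 to 0.885 FPKM in the authors' deposited table. CHAT, the acetylcholine synthesis gene, stood at 0.0686 and 0.368 FPKM and was not tested in the authors' deposited table; it shares its listed locus with SLC18A3, so fragments of the pair are uncertain. The list medians of -0.51 and -0.33 lay at the 94.1st and 93.5th percentiles, and adjusted over the list alone the counts were 2 higher and 8 lower, and 3 higher and 2 lower.

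Of 30 sympathoadrenal neuroblast transcription factor genes, 1 was called higher and 16 lower in the authors' deposited table, with 6 above and 13 below the median gene. SIX3 fell from 6.15 to 0.604 FPKM in the authors' deposited table, beside ID1 and ID2. MYCN stood at 1.36 and 2.02 FPKM in the authors' deposited table (q = 0.472). The list median of -0.77 lay at the 16.3rd percentile, and adjusted over the list alone 5 were higher and 17 lower.

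Of 14 mesenchymal neuroblastoma state genes, 0 were called higher and 5 lower in the authors' deposited table, with 3 above and 3 below the median gene; FN1 (-2.14), NOTCH2 (-1.60) and TWIST1 (-1.49) fell. ZEB2 (-1.23) and VIM (-1.17) were called lower in the authors' deposited table without lying apart from the median gene (adjusted p of 0.222 and 0.102). Of 6 tested glial and Schwann cell markers, the myelin gene PMP22 (1.82) and CD9 (1.69) rose and PDGFRA (-1.84) fell in the authors' deposited table, with 2 above and 1 below the median gene. Of 24 fibroblast and extracellular matrix genes, 1 was called higher and 12 lower in the authors' deposited table, with 5 above and 3 below the median gene. TIMP3 rose, and MMP2 (-1.86) and the collagen gene COL4A2 (-1.74) fell, in the authors' deposited table, while DCN was called lower at -1.96 without lying apart from the median gene (adjusted p = 0.165). Of 20 serum response and actin genes, 0 were called higher and 10 lower in the authors' deposited table, with 4 above and 3 below the median gene. TPM1 (-1.74) and FLNA (-1.52) fell, and AJUBA (-2.08) and SRF (-1.47) were called lower in the authors' deposited table without lying apart from the median gene (adjusted p of 0.217 and 0.247). Medians of these 4 lists were -0.38, -0.39, -0.69 and -0.71, within the range of matched random lists, at the 96.2nd, 80.7th, 25.3rd and 29.4th percentiles. With a mean of at least 5 FPKM the mesenchymal list lay above that range, at 0.37 relative to the median gene, and the fibroblast list below it, at -0.38. Adjusted over the list alone, the higher counts were 0, 2, 1 and 0 and the lower counts 5, 1, 14 and 11.

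Ribosome production genes fell. Of 38 ribosome biogenesis and MYC-associated genes, 33 were called lower in the authors' deposited table and 13 lay below the median gene. MYC itself went from 37.7 to 4.60 FPKM in the authors' deposited table (log2 -3.03, implied standard error 0.370), and UTP20 (-1.90), the ribosomal RNA transcription factor UBTF (-1.80) and DKC1 (-1.73) fell as well. The list median of -1.26 lay below the central 95% of matched random lists, and adjusted over the list alone 35 were lower. Of 61 cytosolic ribosomal protein genes, 37 were called lower in the authors' deposited table, among them RPS9 (-0.98), RPS12 (-0.93), RPL3 (-0.93) and RPS28 (-0.92), but 0 lay apart from the median gene. Their median of -0.59 lay at the 99.2nd percentile, and the sign of its difference from the median gene turned with a pseudocount of 1 or 3 or without the filter on low values. With quantile normalization the list no longer stood apart from matched random lists. Adjusted over the list alone, 49 were lower. Of 77 nuclear-encoded oxidative phosphorylation genes, 40 were called lower in the authors' deposited table and 0 lay apart from the median gene; NDUFA11 (-1.42), NDUFB9 (-1.17), NDUFA6 (-1.16) and NDUFB2 (-1.13) had the largest changes. Their median of -0.73 lay at the 49.4th percentile, with 43 lower when adjusted over the list alone. Of 50 mitochondrial dynamics, import and quality control genes, 1 was called higher and 24 lower in the authors' deposited table, with 2 above and 3 below the median gene. TOMM40 (-1.53), the chaperonin gene HSPD1 (-1.49) and VDAC1 (-1.42) fell, and TFAM was called lower at -1.46 in the authors' deposited table (adjusted p relative to the median gene = 0.0634). That median of -0.76 lay at the 17.9th percentile, with 1 higher and 28 lower when adjusted over the list alone. Genes encoded by the mitochondrial genome were not analysed here.

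Of 29 unfolded protein response and stress genes, 17 were called lower and 0 higher in the authors' deposited table, and 5 lay below the median gene. The chaperone gene HSPA5 (78.9 to 20.5 FPKM), CRELD2 (27.6 to 8.21 FPKM) and PDIA4 (144 to 47.0 FPKM) fell in the authors' deposited table. SDF2L1 was called lower at -1.66 in the authors' deposited table without lying apart from the median gene (adjusted p = 0.263). Of 38 neural chromatin remodelling and repressor genes, 1 was called higher and 23 lower in the authors' deposited table, with 1 above and 6 below the median gene. DPF3, a subunit of the neuronal BAF complex, rose from 0.714 to 3.28 FPKM in the authors' deposited table. REST, which represses neuronal genes in non-neuronal cells, fell from 6.08 to 1.82 FPKM in the authors' deposited table, and HMGB2 (-1.62) and HDAC1 (-1.58) fell too. The medians of these 2 lists, -0.93 and -0.98, lay below the central range of matched random lists, and adjusted over the list alone 18 and 25 were lower and 0 and 1 higher.

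Of 29 cholesterol synthesis genes, 1 was called higher and 3 lower in the authors' deposited table, but 9 lay above the median gene and 0 below it. MSMO1 rose from 24.5 to 46.0 FPKM in the authors' deposited table. SCD (-0.90) and ACLY (-0.64) were called lower in the authors' deposited table and did not lie apart from the median gene, and the sign for ACLY turned when FPKM were rescaled to an equal sum or quantile normalized. The equal-sum scaling raises every log2 fold by 0.78, so that turn is not particular to ACLY. Of 36 lysosome and autophagy genes, 3 were called higher and 3 lower in the authors' deposited table, with 7 above and 0 below the median gene. The autophagy genes GABARAPL1 (2.30), MAP1LC3A (1.31) and WIPI1 (1.19) rose, and CTSA was called lower at -0.92 in the authors' deposited table (adjusted p relative to the median gene = 0.757). Of 28 p53 target and apoptosis genes, 2 were called higher and 7 lower in the authors' deposited table, with 7 above and 0 below the median gene. GDF15 (0.202 to 3.44 FPKM) rose in the authors' deposited table beside CDKN1A. TP53I3 (-2.40) and BCL2 (-1.70) were called lower in the authors' deposited table, with adjusted p relative to the median gene of 0.050 and 0.112. Of 9 tested interferon response genes, 0 were called higher and 1 lower in the authors' deposited table, with 1 above and 0 below the median gene. The medians of these 4 lists, -0.03, -0.23, -0.27 and 0.09, lay above the central range of matched random lists. Of 27 hypoxia and glycolysis genes, 1 was called higher and 12 lower in the authors' deposited table, with 3 above and 1 below the median gene. BHLHE40 (1.87) rose and ENO1 (-1.46) fell, and SLC2A1 (-1.34) and GPI (-1.30) were called lower in the authors' deposited table with adjusted p relative to the median gene of 0.166 and 0.056. Their median of -0.82 lay at the 8.79th percentile. Adjusted over the list alone, the higher counts of these 5 lists were 1, 2, 3, 0 and 1 and the lower counts 3, 0, 7, 1 and 12.

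The count of lower genes rests on the FPKM scale: relative to the median gene it went from 3518 to 509. The table gives no value per library, so no named gene could be checked for separation between the 2 libraries of each group.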

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

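The alternative with at least 1 FPKM in both groups (181 higher, 3400 lower) and the one that subtracted the olfactory receptor background were chosen after seeing the data. No paired analysis was possible because the table holds 1 value per group and no values per library. For the same reason the other variance models, the replicate block, leaving out each library, camera with an estimated correlation and fry were not run; a pseudocount gave no count of calls, since the authors' calls were used, and taking the highest row per symbol changed nothing to test, since no gene symbol repeats. The 246 higher and 3518 lower calls depended most on the scaling. Median-of-ratios scaling gave 1139 calls, 630 higher and 509 lower. With 1 value per group it is the same calculation as the comparison with the median gene, so the equal counts are no separate check. Rescaling to an equal sum gave 1208, with 895 higher and 313 lower, and quantile normalization gave 1041, with 569 and 472. These scalings raise the log2 folds by 0.62, by 0.78 and, as a median over genes, by 0.60. A mean of at least 5 FPKM left 111 higher genes, and a log2 fold of at least 1 left 2271 calls, 2077 of them lower; in both, fewer genes can pass by construction. Of 29 lists, 18 stood apart from matched random lists. The postsynaptic list no longer did with a pseudocount of 3 or without the filter on low values, nor the cytosolic ribosomal protein list with quantile normalization. With a mean of at least 5 FPKM, 16 of 25 lists stood apart: the retinoic acid response and ion channel lists no longer did, and the mesenchymal and fibroblast lists did. The cytosolic ribosomal protein median relative to the median gene was 0.03, and turned to -0.0707 with a pseudocount of 1, -0.198 with a pseudocount of 3 and -0.00833 without the filter on low values. Without the filter the HOX list (0.580 to 0.541) and the oxidative phosphorylation list (-0.104 to -0.143) moved alike, since the median gene itself moved. The cause of the turn with a pseudocount was not tested. With quantile normalization the relative medians of the oxidative phosphorylation list (to 0.006) and the hypoxia list (-0.19 to 0.06) turned too. The catecholamine one turned with a pseudocount of 3 (0.12 to -0.02). Of 118 reported genes with a usable fold change, 26, 38 and 27 lost their call under median-of-ratios, sum and quantile scaling. Signs turned for HOXC4 (0.53, 0.69 and 0.50 under these scalings), which was not called, and for ACLY (0.15 and 0.10 under the sum and quantile scalings). Median-of-ratios and sum scaling raise every gene by the same amount, so a negative fold smaller than that amount has to turn positive. A pseudocount of 0.1, 1 or 3 moved 1, 37 and 66 of the 118 by more than their implied error (CACNA2D3 from 5.43 to 2.15 and 1.15, and NTRK2 from 3.91 to 2.29 and 1.37, with 1 and 3), and subtracting the olfactory receptor background moved 0. Depth per library is unknown, which leaves genes near 0 without a detection limit.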

Other observations

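The tests on scale, transcript length, amount of messenger RNA and sequencing depth were chosen after the results they measure were seen. The single-exon test and its multi-exon comparison were added after the tissue-restricted test was seen, as were the intervals of the ratios and the ratio without the 4 genes that the authors tested; the fold without OR7E12P was also added after its values were seen.

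Targets of bone morphogenetic protein (BMP) signalling fell beside ID1 and ID2. ID3 went from 10.2 to 1.19 FPKM in the authors' deposited table, and lay below the median gene (adjusted p = 0.00694). A hypothesis of lower signalling through BMP receptors was tested on 6 other BMP target genes. Their median log2 fold was -2.29, at percentile 0 of matched random lists, with a central range from -1.07 to 0.06. SMAD9 (-1.94), TBX20 (-3.79) and UNC5B (-2.28) fell in the authors' deposited table and lay below the median gene. SMAD6 (-4.74) and SMAD7 (-2.30) were called lower in the authors' deposited table without lying apart from the median gene (adjusted p of 0.132 and 0.167), and ID4 (1.10) rose. The result is consistent with lower signalling through BMP receptors in the differentiated cells, but the removal of serum came with the differentiation and cannot be separated from it.

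The imprinted genes H19, IGF2 and DLK1 rose together. IGF2 went from 63.9 to 185 FPKM and DLK1 from 402 to 1153 FPKM in the authors' deposited table, with log2 fold changes of 1.54 and 1.52. A joint rise of imprinted genes was tested on 21 others, whose median of -0.52 lay at percentile 79.1 of matched random lists, so the test did not decide. GPR1 was called higher (log2 2.66) and PEG10 (-0.84), RTL1 (-0.94) and PPP1R9A (-1.44) lower in the authors' deposited table. GPR1, GNAS and ZDBF2 lay above the median gene, and 0 lay below it.

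Far more genes were called lower than higher. A bias by transcript length is argued against, since the median folds of the shortest and longest 20% of transcripts differed by 0.139, against a median fold of -0.62. The sum of FPKM times transcript length over listed genes, without small RNAs, changed by a log2 ratio of -0.71. If FPKM was scaled to all mapped fragments, that sum went from 66.7% to 40.9% of fragments. It has to fall when most genes do, so it does not test the cause. A different scale between the groups, with more fragments counted outside the listed genes in differentiated cells, and less messenger RNA per unit of total RNA (median log2 fold -0.62) both stay open and cannot be told apart, because no added standard was analysed here.

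Genes that are silent in most cells were listed above 0 more often in differentiated cells: of 395 olfactory receptor genes, 28 were above 0 before and 259 after, and their mean FPKM rose 6.75-fold, from 0.0114 to 0.0773 (11.6-fold without the pseudogene OR7E12P, the most abundant before, at 1.99 and 1.12 FPKM in the authors' deposited table). A change in depth alone would leave that mean in place, and an induction of particular receptors would be held by few genes, whereas the 20 largest rises held 26.0% of the total. Fragments spread over the whole genome, such as genomic DNA, stay open: the rise of 75 tissue-restricted genes was 0.0399 times that of the receptor genes, under the 0.2 set beforehand as speaking against it, but its interval from -0.430 to 0.493 spans that bound, as does that of 0.141 to 0.423 around the ratio of 0.261 without the 4 genes that the authors tested. Counting mainly where a transcript is a single exon stays open too, since 309 other single-exon genes with a mean under 0.1 FPKM and a transcript of at least 800 bases rose 0.478 times as much as the 344 receptor genes under the same limits (interval 0.370 to 0.603), just short of the 0.5 set beforehand, and 3984 multi-exon genes under these limits rose 0.292 times as much (interval 0.254 to 0.345), with 2145 higher and 630 lower. Low transcription across silent chromatin in differentiated cells was not tested.

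The row named for the ribosomal RNA precursor RNA45S5 went from 168 to 299 FPKM in the authors' deposited table, in libraries made after ribosomal RNA removal. Its log2 fold change was 0.83 (q = 0.000522). The value does not separate precursor from ribosomal RNA left after that removal, so it is not read as a rise of the precursor.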
